A study of Mus musculus with 12 samples.

How the data were processed

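RNA was sequenced from small bowel of male C57BL/6 mice in 12 libraries. The labels give 4 groups of 3 libraries: before ileocecal resection (removal of the last part of the ileum and the cecum) in a control arm (Pre control) and in an arm assigned to 2'-fucosyllactose (2'-FL, a human milk oligosaccharide; Pre 2'-FL), and after resection without the supplement (Post control) and with it (Post 2'-FL). Per the labels, mice were 8 to 10 weeks old, the supplement was given at 2.5 g/L from day 0, the day of resection, and libraries were made with the TruSeq RNA kit from about 1.5 µg of RNA and sequenced on a HiSeq 2000. The labels place the collection of all bowels at 8 weeks after resection, although 6 libraries are labelled as taken before it; the labels of the single libraries were followed. The labels also name a liquid diet with day 7, and give this entry and the age alike for all 12 libraries. The labels do not give the segment of bowel, the hour of collection, or whether libraries with the same number before and after resection came from the same mouse.

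Each deposited file holds 1 library with estimated raw read counts per gene (expected counts), which the authors had not normalised. The labels name the mm10 build and DESeq. The aligner, the counting program, the gene annotation and the strand are not given in the labels. Between 15.2% and 20.5% of the entries of a library are fractional, so part of the reads had been divided between genes or places. Related genes, such as the defensins or Gsta1 and Gsta2, may share such reads. They were tested as separate genes, and how far they share reads was not tested. Genes carry Entrez identifiers. Of the 36186 entries, 486 belong to genes listed at more than 1 place; the entries of a gene were summed, which left 35791 genes, and sums were rounded to whole counts. Totals ran from 5663275 to 9385266 counts per library, so that 1 count corresponded to between 0.100 and 0.189 CPM (counts scaled to the library total). Floors of 3 counts, given where a group held none, cover counting error only, since reads are not independent molecules.

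Differential expression was tested in R 4.3.3 with edgeR 4.0.16. Genes were kept with filterByExpr by group, which left 13154, libraries were scaled with TMM, and 1 quasi-likelihood model with a mean for each group was fitted to all 12 libraries, with 8 residual degrees of freedom and a biological coefficient of variation of 0.238. Every adjusted p of a gene comes from edgeR's quasi-likelihood F test with Benjamini-Hochberg adjustment over the 13154 genes, two-sided, and a gene was called at an adjusted p under 0.05. A p from this model measures spread between libraries. A standard error (SE) of a log2 fold change is the fold change divided by the square root of F. The values in CPM use the TMM-scaled library sizes and stand with the standard deviation (SD) over 3 libraries. The comparisons were Post against Pre within each arm, Post against Pre over both arms, 2'-FL against control within Post and within Pre, and the interaction (the change in the 2'-FL arm minus the change in the control arm).

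Before the data were examined, the groups, comparisons, test, thresholds, most alternatives, 35 gene lists and the rule for named genes were fixed. The lists cover segment identity, epithelial and other cell types, absorption, lipid and energy metabolism, defence, clock and stress genes. They were tested with camera in limma 3.58.1 with a preset correlation between genes of 0.01, adjusted over the lists within a comparison, and again with an estimated correlation and with fry. The pancreas list had no tested member, which left 34. Beside each list stand its members called over all genes and those called when adjusted over the list alone. Called gene lists describe sets of members and not the reason for a change. Named genes are the 10 largest changes each way with an adjusted p under 0.05, a mean of at least 5 CPM in the groups compared and no overlap between their single libraries (5 each way in the interaction and between the Pre groups, in the interaction without the overlap condition), without unnamed gene models, plus up to 4 members of a list with the smallest p. Where fewer than 5 genes passed, the 5 smallest p were taken. Fut2, Fabp6, Fgf15, Reg3b and Reg3g were always to be given.

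After the counts had been examined, levels in most libraries were found to follow transcript length, and a correction was added. Length and GC content were taken from the GENCODE mouse annotation of mm10, as the longest transcript matched to a curated RefSeq mRNA, for 13049 of the 13154 genes. The first choice had been the protein-coding transcript of middle length. It gave fragments for known long mRNAs and was replaced after its results were seen, and it is kept as an alternative. In every library, log2 CPM centred per gene (prior count 2) was fitted by natural splines with 4 degrees of freedom on length and on GC, and the fitted values entered the edgeR model as offsets. Such an offset also removes any difference between mice that itself follows length. Coordinates are from the same annotation on mm10.

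Alternatives fixed in advance were RLE size factors, DESeq2 1.42.0, limma-voom, no count filter, a stricter filter (over 1 CPM in 3 libraries and a mean of 5 CPM), library sizes without the 50 most abundant genes, a fit of only the groups compared, the replicate number as a block, arm by replicate number as a block, an adjusted p under 0.1, a change of at least 2-fold, and leaving out each library. Added later were the length and GC correction, the same with the replicate block, its version with the transcript of middle length, removal of Esp38 and Lars2, and removal of 2 libraries, Post 2'-FL 1 (strongest GC trend) and Pre control 3 (highest Esp38 share).

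The procedure was tested on simulated counts with the real library sizes, means and dispersions. In Post against Pre of the control arm, without a length trend, 45 of 100 genes changed 2-fold and 95 of 100 changed 4-fold were recovered, and 7 unchanged genes were called among 12866. With a length trend put into the Post 2'-FL libraries, 1818 unchanged genes of 12832 were called between the Post groups without the correction and 9 with it, and the corrected model recovered 43 of 100 and 99 of 100. In the interaction, the trend gave 429 unchanged genes without the correction and 6 with it, and the corrected model recovered 10 of 100 and 77 of 100. The simulated trend was alike in all Post 2'-FL libraries, linear in the lengths used by the correction, and without a GC trend. Real libraries differ from each other in both trends, so these runs test the correction only for a trend of that form. A list raised by 1 log2 unit was called by camera with an adjusted p of 2.32e-25 and 0 of the other lists were called. The simulated genes varied independently of each other. This run therefore cannot show how camera with the preset correlation behaves where genes of a list vary together.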

Results

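Small bowel RNA was counted in 12 libraries from male C57BL/6 mice, 3 in each of 4 groups: Pre control, Pre 2'-FL, Post control and Post 2'-FL, where Pre and Post stand for before and after ileocecal resection. The series addresses how the remaining bowel adapts to this resection and whether 2'-FL, a fucosylated milk sugar, changes that. Totals were 7869012, 9385266 and 8624519 counts in Pre control 1 to 3, and 7081702, 5807163 and 5663275 in Pre 2'-FL. After resection they were 6244091, 5692972 and 9321751 in Post control, and 6603864, 6781258 and 6143667 in Post 2'-FL. At this depth 13154 genes could be tested. The first principal component of log2 CPM held 54.5% of the variance and the second 19.0%.

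Transcript length went with group in most libraries. Across genes, which are not independent replicates, Spearman's rho between transcript length and the log2 level relative to the gene's mean was 0.42, 0.45 and 0.26 in Pre control and 0.50, 0.39 and 0.36 in Pre 2'-FL. It was -0.04, -0.21 and 0.35 in Post control, and -0.44, -0.56 and -0.60 in Post 2'-FL. The 1305 genes with the shortest transcripts (216 to 1222 nt) had a median deviation of 0.97, 0.55 and 0.86 log2 units in the Post 2'-FL libraries, and those with the longest (from 6481 nt) one of -0.70, -0.55 and -0.75. The labels name no batch, so that no value within a batch can be given. The trend lies mostly with the groups, although Post control 3 lay within the range of the Pre libraries. Each comparison is therefore also given with length and GC corrected. Esp38, annotated as an exocrine gland secreted peptide gene, took from 0.398% (Post control 3) to 14.1% (Pre control 3) of the counts of a library. Lars2 was lowest and highest in the same libraries, at 0.276% and 1.68%. Whether the reads counted for Esp38 come from that gene was not tested.

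**Figure D1:**
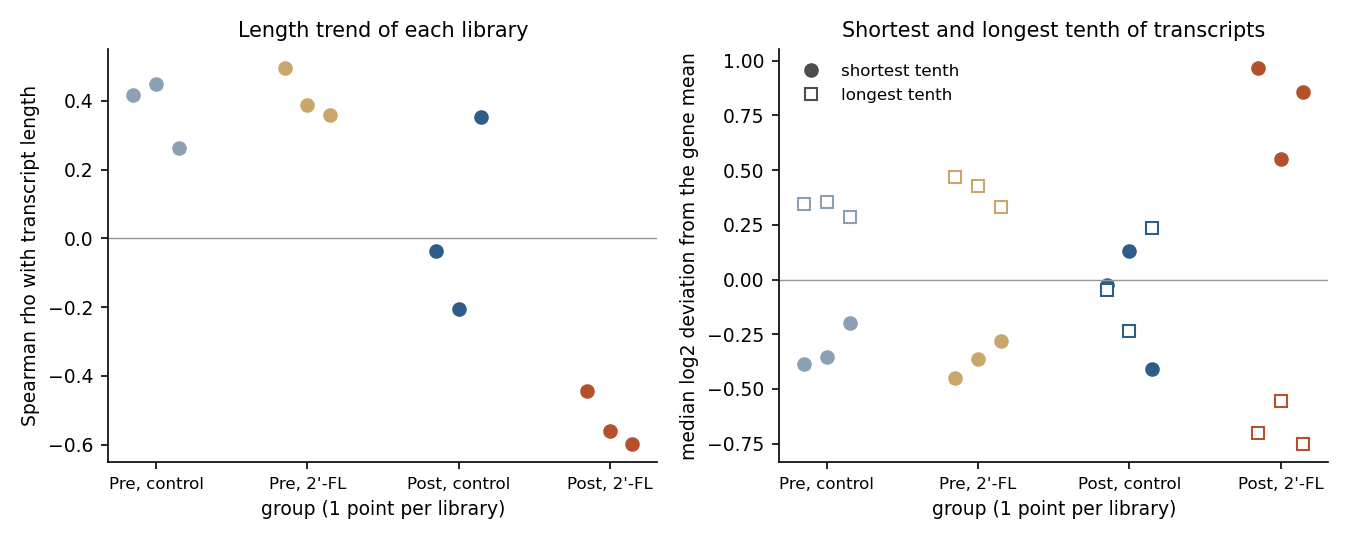
Length trend of each of the 12 libraries. Left, Spearman's rho across genes between transcript length and the level relative to the gene's mean; right, the median log2 deviation of the 1305 genes with the shortest (filled circles) and the longest (open squares) transcripts, with 1 point per library. The 3 Post 2'-FL libraries lie between -0.44 and -0.60 on the left, and the 6 Pre libraries between 0.26 and 0.50.

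Post against Pre in the control arm asks what differed after resection without the supplement. Age, diet and bowel segment may also differ between Pre and Post libraries. The labels do not let these be told apart from resection in either arm. The ileal genes Fgf15 and Cubn, 15 of 16 Paneth cell genes, 8 of 12 crypt stem cell genes and 12 of 23 cell cycle genes were lower after resection. The carboxylesterase gene Ces1f and 7 of 22 interferon response genes were higher. Fgf15, the ileal hormone that restrains bile acid synthesis in the liver, averaged 12.4 ± 12.1 CPM (SD, n = 3) in Pre control and had 0 counts in each of the 6 Post libraries. Against a floor of 3 counts per library its group mean was at least 28.3-fold lower in this arm (adjusted p = 0.0205), and 14.5-fold without Pre control 2. Pre control 3 itself lay near such a floor: without it the mean was 18.4 CPM and the bound 42.1-fold. The mean thus rests on Pre control 1 and 2. Ces1f, a carboxylesterase gene (Entrez 234564, chromosome 8, 93256236 to 93279747), rose from 9.05 ± 4.78 to 123 ± 45.4 CPM (SD, n = 3), a log2 change of 3.75 ± 0.46 (SE, adjusted p = 0.000965). Abca1, the cholesterol efflux transporter (Entrez 11303, chromosome 4, 53030787 to 53159895), fell from 91.8 ± 43.1 to 6.83 ± 0.379 CPM, a log2 change of -3.74 ± 0.34 (adjusted p = 0.000278).

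By the rule for named genes, the other large increases in this arm, in log2 units, were Oas1e at 6.15, Rsad2 at 2.68 and Apol9a at 2.78, which belong to interferon-induced gene families, Onecut2, a transcription factor, at 3.45, and Cox6b2, a cytochrome oxidase subunit, at 2.92. They also include Angptl4, an inhibitor of lipoprotein lipase (Entrez 57875, chromosome 17, 33773750 to 33781830), at 2.80, Tmem252 at 2.69, Mfsd7c at 2.63 and Mcpt1, a mast cell protease, at 2.60. The other large decreases were the clock-controlled transcription factors Dbp (Entrez 13170, chromosome 7, 45705088 to 45710203) at -6.59 and Hlf at -3.73, the clock gene Per3 at -3.47, Esp38 at -3.66, Serpina1b at -3.28, the Paneth cell defensins Defa20 and Defa2 at -2.93 and -2.89, and Habp2 at -2.85. In each of these genes the 3 Post libraries lay on 1 side of the 3 Pre libraries, and each was still called with length and GC corrected. Fabp6, the ileal bile acid binding protein, changed by -6.46 ± 1.74 (adjusted p = 0.0321) with overlapping libraries. It rests on Pre control 2, which held 166 CPM: without that library the change was -2.63, and it was not called without that library or any 1 of the Post control libraries (-6.16, -6.86 and -6.38). Also not called were Fgf15 without Post control 1 or 2 (adjusted p = 0.0644 and 0.074), Esp38 without Post control 1 (-3.56), Mcpt1 without Pre control 3 or Post control 1 (2.89 and 1.58), and Mfsd7c without Pre control 2, Pre control 3 or Post control 1 (2.68, 2.46 and 2.65). Without Pre control 3 Oas1e was at 7.35, Onecut2 at 4.19 and Esp38 at -2.87. Reg3b (0.11 ± 0.69), Reg3g (0.48 ± 0.71) and Fut2 (0.27 ± 0.77) were not called.

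Of the 34 lists in the control arm 17 passed camera, and 0 with an estimated correlation, which gave these lists adjusted p values from 0.379 to 0.658. Corrected, 16 passed and 0 with an estimated correlation (adjusted p from 0.359): the immediate early (0.0721), T cell (0.109) and xenobiotic (0.235) lists no longer did, and the goblet cell and B cell lists did (0.0368 each) with 0 genes called. Of 69 called list genes examined singly, 51 were not called without at least 1 of the libraries and 10 when corrected. Among the gene lists, 15 of 16 Paneth cell genes fell (15 corrected), with a median log2 change of -1.91. Among them Defa22 changed by -2.81 ± 0.52 and Defa21 by -2.78 ± 0.52. The defensin genes of this list may share divided reads, so its genes are not separate observations. Of 12 crypt stem cell genes 8 fell (7 corrected), and 9 adjusted over the list alone. Of 23 cell cycle genes 12 fell (14 corrected), and 16 adjusted over the list alone, led by the replication helicase genes Mcm6 (-1.21) and Mcm3 (-1.35). Of 10 neuron and glia genes 5 fell (7 alone, 5 corrected), of 13 extracellular matrix genes 4 (8 alone, 2 corrected), and of 7 endothelial genes 1 (5 alone, 0 corrected). Among 12 clock genes 7 fell and 2 rose, Dbp and Per3 down and Arntl, which peaks in the opposite phase, up by 2.60 ± 0.29. Adjusted over the list alone 8 fell and 4 rose, and corrected 7 and 4. Of 22 cholesterol synthesis genes 5 rose (6 corrected) and 15 when adjusted over the list alone. Of 22 interferon response genes 7 rose (7 corrected), with Isg15 at 2.15. Of 12 xenobiotic genes 5 rose and 2 fell (4 and 2 corrected), with Abcb1a at -2.22 and Ces2a at -2.31 lower. The distal small bowel list did not pass camera (adjusted p = 0.0816, 0.0523 corrected), and 3 of its 7 genes fell (3 corrected), the third beside Fgf15 and Fabp6 being Cubn, the ileal receptor for cobalamin uptake, at -2.54. In other lists that passed as tested, 3 of 12 myeloid genes, 3 of 4 red blood cell genes and 2 of 13 smooth muscle genes fell, as many as corrected, and 3 of 14 growth factor genes (2 corrected, where 1 rose). In the immediate early list 2 of 12 genes rose (3 corrected), in oxidative phosphorylation 1 of 34 (1 corrected), and in the T cell list, whose median was 0.78, 1 of 16 fell (0 corrected) and 0 rose.

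In all, 1415 of the 13154 genes were called in the control arm, 582 higher and 833 lower, and 4589 genes had groups that did not overlap, 34.9% where chance gives 10%. After the correction 1656 were called, 985 higher and 671 lower, 1059 of them shared with the 1415. The share of higher genes went from 41.1% to 59.5%. The number fell to 626 without Pre control 2, 340 without Pre control 3, 350 without Post control 1, 265 without Post control 2 and 570 without Pre control 3 and Post 2'-FL 1.

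**Figure D2:**
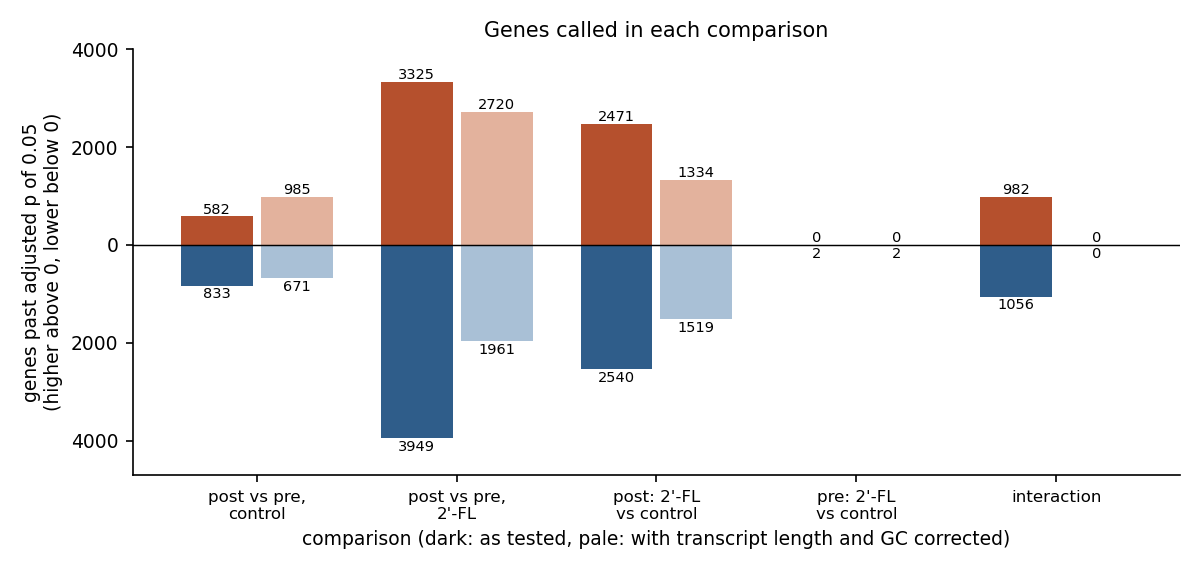
Number of genes called in each of 5 comparisons, higher above 0 and lower below 0, as tested (dark bars) and with transcript length and GC corrected (pale bars). The control arm has 582 higher and 833 lower genes as tested and 985 and 671 corrected, and the interaction has 982 and 1056 as tested and 0 corrected.

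Post against Pre in the 2'-FL arm asks the same with the supplement. Fgf15 and Ces1f were among the largest changes in this arm too. The glutathione transferases Gsta1 and Gsta2 were also among the largest increases, and Irs2 and Flt1 among the largest decreases. Ces1f rose from 5.76 ± 0.287 to 207 ± 112 CPM (SD, n = 3), a log2 change of 5.16 ± 0.50 (SE, adjusted p = 2.96e-05), and the neighbouring Ces1g (Entrez 12623, chromosome 8, 93302369 to 93337308) by 4.46 ± 0.76 (3.09 without Post 2'-FL 3). Irs2, an insulin receptor substrate (Entrez 384783, chromosome 8, 10984681 to 11008458), fell from 21.1 ± 4.6 to 0.568 ± 0.328 CPM, a log2 change of -5.15 ± 0.56 (adjusted p = 3.14e-05). Fgf15 went from 11.7 ± 9.24 CPM to 0 counts and was at least 22.1-fold lower (adjusted p = 0.00448), and 12-fold without Pre 2'-FL 2.

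The other large increases in the 2'-FL arm were Map3k12 at 3.87, Sprr2a3 at 3.76, the glutathione transferases Gsta1 and Gsta2 at 3.68 and 3.59, the alcohol dehydrogenase Adh4 at 3.52, Cox6b2 at 3.46, the protease inhibitor Slpi at 3.07 and Akr1c19, an aldo-keto reductase, at 3.00. In Pre control, Pre 2'-FL, Post control and Post 2'-FL, Gsta1 averaged 31.7, 19.5, 95.4 and 251 CPM. Gsta2 averaged 5.28, 3.29, 15.9 and 40.3 CPM in the same order. These genes may share reads, so their increases are not shown to be separate. Other large decreases were the desaturase Scd1 at -4.26, the vascular growth factor receptor Flt1 at -3.97, Soga1 at -3.93, Car3 at -3.89, Cubn at -3.85, the lipid droplet gene Plin4 at -3.82 and Cbfa2t3 at -3.78. The genes named in this arm for the largest changes were still called with length and GC corrected, with smaller changes for most, as for Gsta1 at 2.40 and Soga1 at -2.19. Car3 was not called without Pre 2'-FL 1 (-2.16), the library in which it stood at 219 CPM, and was at -4.70 without Post 2'-FL 1. Without Pre 2'-FL 1 Plin4 was at -2.34, Scd1 at -3.04 and Adh4 at 4.34, and without Post 2'-FL 1 Scd1 was at -5.60. Without Post 2'-FL 2 Sprr2a3 was at 2.02, Flt1 at -4.62, Plin4 at -4.85 and Cbfa2t3 at -4.38, and without Post 2'-FL 3 Gsta1 was at 3.08 and Gsta2 at 2.99. Reg3b rose by 2.44 ± 0.73 (adjusted p = 0.0113) and Reg3g, which like Reg3b encodes an antibacterial lectin, by 1.97 ± 0.73 (adjusted p = 0.0338). With length and GC corrected they changed by 0.95 ± 0.61 and 0.57 ± 0.63 and were not called, nor were they without Post 2'-FL 1 (1.97 and 1.63). Reg3g was also not called without Pre 2'-FL 1 (1.62), Pre 2'-FL 3 (2.19) or Post 2'-FL 3 (1.89). Fut2 (-0.70 ± 0.64) and Fabp6 (-2.26 ± 1.76) were not called.

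Of the 34 lists in the 2'-FL arm 3 passed camera (oxidative phosphorylation, cholesterol synthesis and endothelium), and 0 with an estimated correlation (adjusted p = 0.952 each). Corrected, 7 passed, with the Paneth cell, myeloid, neuron and glia and adipose lists added, and 0 with an estimated correlation (adjusted p = 0.694 each). Of 121 called list genes examined singly, 20 were not called without at least 1 of the libraries and 42 when corrected. Of the lists, 29 of 34 oxidative phosphorylation genes rose and 1 fell, with a median of 1.42, and Ndufb8 at 2.19 ± 0.24, Ndufv2 at 1.98 ± 0.23 and Ndufb9 at 2.15 ± 0.25. Corrected for length and GC, 19 rose, 2 fell and the median was 0.45. Cholesterol synthesis rose in 16 of 22 genes and fell in 1, with Pmvk at 2.27, Mvk at 1.98 and Idi1 at 2.22. Corrected, 17 rose and the median went from 1.00 to 1.31. All 7 endothelial genes fell, with Pecam1 at -2.37, Flt4 at -3.12 and Cdh5 at -2.41, and 4 of them when corrected. Of 16 Paneth cell genes 5 fell and 1 rose; corrected, 15 fell and the median went from -0.65 to -1.93. Of 12 stem cell genes 7 fell (1 corrected), with Rnf43 at -1.40 (-0.33 corrected, not called), of 12 clock genes 7 fell and 1 rose (3 and 1 corrected), with Per2 at -1.88 (-0.63 corrected, not called), and of 10 neuron and glia genes 5 fell (6 corrected), with Ret at -1.93. Of 7 adipose genes 5 fell, with Plin1 at -4.41 (-3.06 without Pre 2'-FL 1). These genes stood apart in Pre 2'-FL 1, where Adipoq was at 48.5 CPM and at 5.63 and 7.12 CPM in the other 2 libraries.

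In all, 7274 genes were called in the 2'-FL arm, 3325 higher and 3949 lower, and 8103 had groups that did not overlap (61.6% where chance gives 10%). The correction left 4681 called, 2720 higher and 1961 lower, 3473 of them shared, and the share of higher genes went from 45.7% to 58.1%. The median log2 change over all genes was -0.13 as tested and 0.01 corrected.

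**Figure D3:**
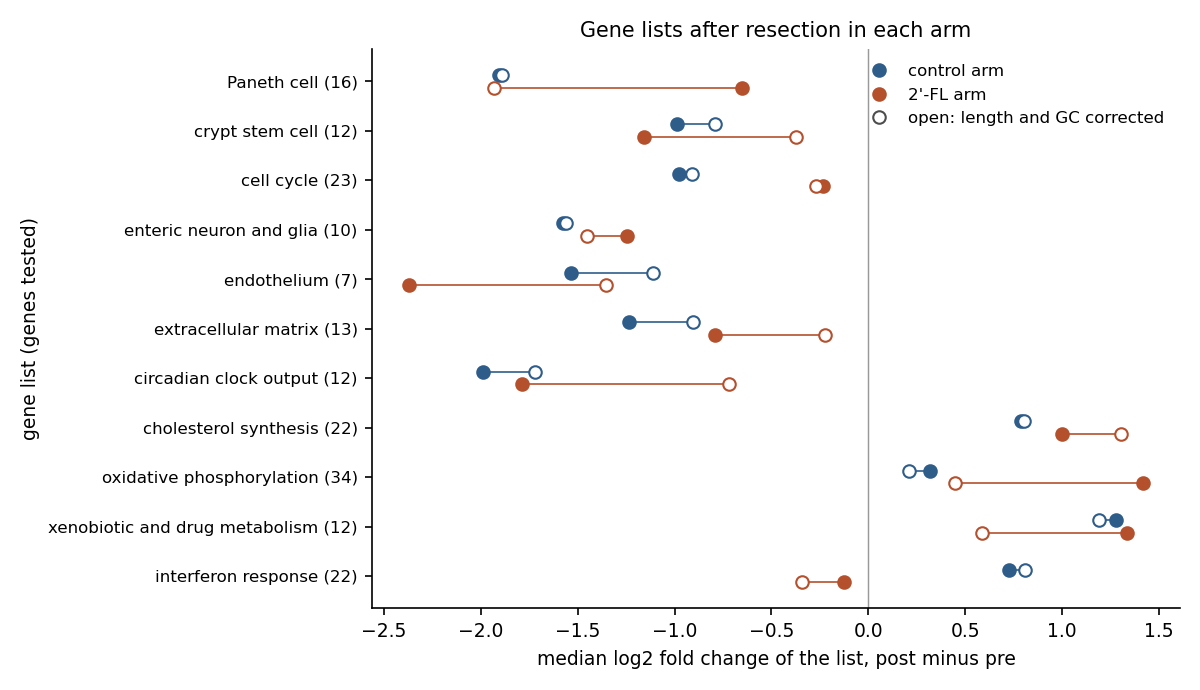
Median log2 fold change, post minus pre, of 11 gene lists in the control arm (blue) and the 2'-FL arm (red), as tested (filled) and with transcript length and GC corrected (open). The Paneth cell list lies at -1.91 in the control arm and at -0.65 in the 2'-FL arm as tested, and at -1.89 and -1.93 corrected.

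Averaged over both arms, 6 Post against 6 Pre libraries, the ileal gene Cubn fell by 3.20 ± 0.30 on the log2 scale (adjusted p = 1.55e-05), Dbp by 4.95 ± 0.46 and the growth factor receptor Igf1r by 2.32 ± 0.27. Corrected, these fell by 2.38, 4.78 and 1.36. Isg15 rose by 2.06 ± 0.19, Pmvk by 1.83 ± 0.20, Gsta1 by 2.63 ± 0.30 and Angptl4 by 2.31 ± 0.28, and corrected by 1.49, 1.55, 1.91 and 2.61. Of 16 Paneth cell genes 15 fell, as tested and corrected. Cholesterol synthesis rose in 16 of 22 genes (18 corrected), oxidative phosphorylation in 29 of 34 (21 corrected), with 1 gene lower as tested in each of these lists, and 9 of 12 stem cell genes fell (6 corrected). Neuron and glia genes fell in 8 of 10 (9 corrected) and endothelial genes in all 7 (6 corrected). The arms differed in 2 of these lists. Corrected, oxidative phosphorylation rose in 1 gene in the control arm, and in 19, with 2 lower, in the 2'-FL arm. Endothelial genes fell in 0 and 4 in the same order. Reg3b was called at 1.27 ± 0.50 (adjusted p = 0.0406) and not when corrected (0.39 ± 0.43, adjusted p = 0.479). Nor was it called without Pre control 1 or 2 (1.18 and 1.27), Pre 2'-FL 1 (1.13), Post control 2 (0.61) or Post 2'-FL 1 or 3 (1.04 and 1.28). Reg3g was not called at 1.22 ± 0.51 (0.42 ± 0.45 corrected), and was without Pre control 3 (1.67), Pre 2'-FL 2 (1.43), Post control 1 or 3 (1.46 and 1.43) or Post 2'-FL 2 (1.40). Fabp6 was called at -4.36 ± 1.23 (-4.89 ± 1.26 corrected). It was at -2.42 without Pre control 2, and at -2.55 and not called without Pre 2'-FL 2 (adjusted p = 0.243). In all, 7416 genes were called, 3329 higher and 4087 lower. Corrected, 5704 were called, 3229 higher and 2475 lower. The share of higher genes went from 44.9% to 56.6%, and the median over all genes from -0.10 to 0.02. Of 34 lists 9 passed camera and 0 with an estimated correlation, where the smallest adjusted p was 0.831. Corrected, 11 passed, without the xenobiotic list (0.488) and with the goblet cell, myeloid and red blood cell lists, and 0 with an estimated correlation (smallest adjusted p 0.659).

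**Figure D4:**
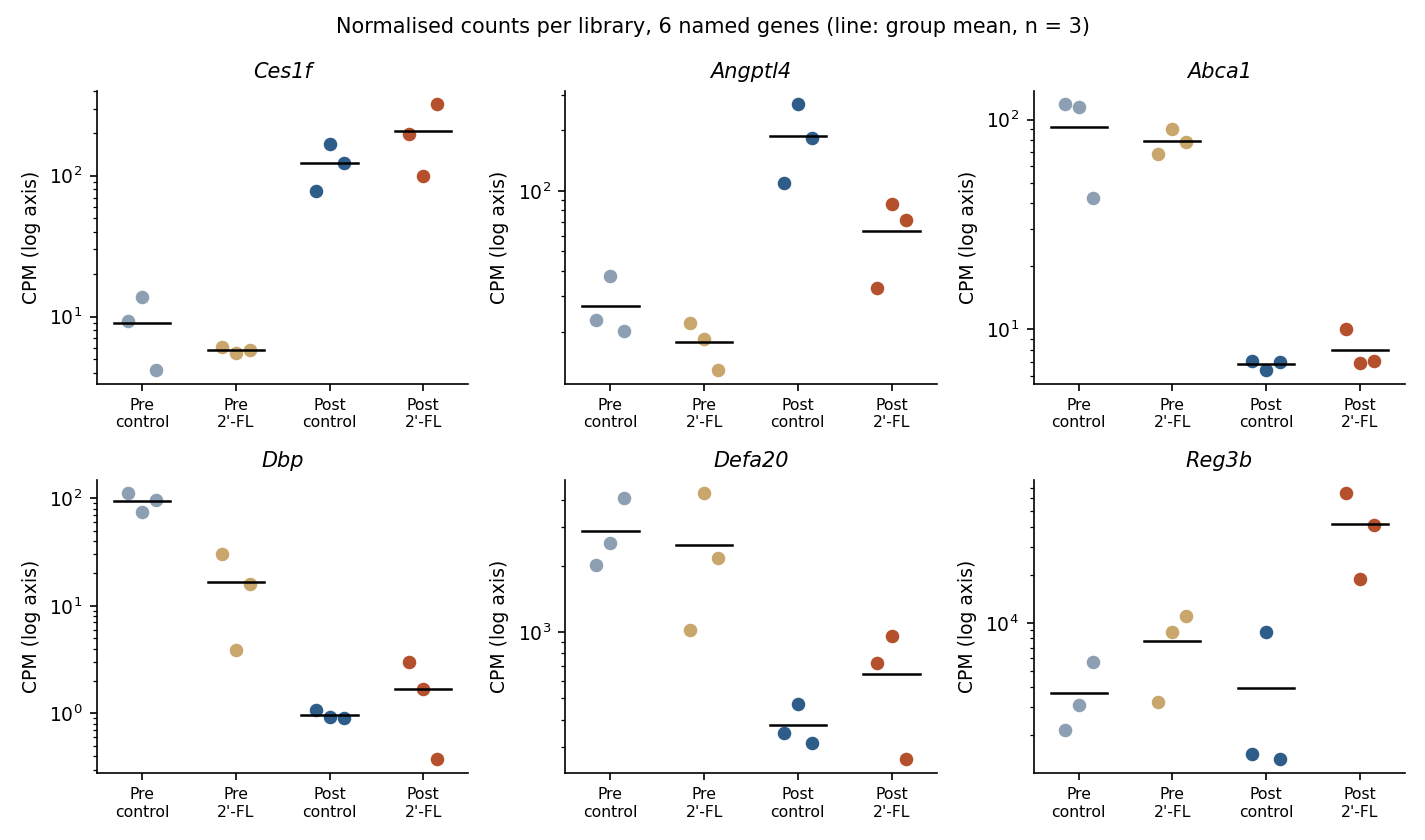
Normalised counts (CPM, log axis) of 6 genes in the 12 libraries, 1 point per library, with a line at the group mean (n = 3). Ces1f and Angptl4 are higher and Abca1, Dbp and Defa20 lower in Post control than in Pre control, and Reg3b averages 41577 CPM in Post 2'-FL and 3905 CPM in Post control.

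Post 2'-FL against Post control asks how supplemented bowel differed from unsupplemented bowel after resection. The antibacterial lectin genes Reg3b and Reg3g were higher with the supplement, and the 10 largest decreases were all in genes with long transcripts. Reg3b (Entrez 18489, chromosome 6, 78370657 to 78373466) averaged 41577 ± 23073 CPM against 3905 ± 4239 CPM (SD, n = 3), a log2 difference of 3.41 ± 0.76 (SE, adjusted p = 0.00355), and Reg3g (Entrez 19695, chromosome 6, 78466269 to 78468872) 14108 ± 6813 against 2279 ± 2168 CPM, a difference of 2.63 ± 0.75 (adjusted p = 0.0138). Corrected, Reg3b was 2.20 ± 0.63 higher (adjusted p = 0.0254) and Reg3g 1.46 ± 0.64 (adjusted p = 0.116, not called). Reg3g was also not called without Post control 3 (2.37) or without Post 2'-FL 1 (2.29), and without Post control 2 Reg3b was at 4.89 and Reg3g at 3.83. Kif13b, a kinesin (Entrez 16554, chromosome 14, 64647265 to 64809617), averaged 2.65 ± 1.18 against 22.5 ± 7.02 CPM, a difference of -3.06 ± 0.32, and -2.34 ± 0.27 corrected (adjusted p = 0.00281).

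The other genes with the largest increases were Cntd1 at 4.44, Saa1, an acute phase protein, at 3.34, Pla2g5 at 2.44, Defa-ps1 at 2.41, the neuropeptide Vip at 2.35, Hddc2 at 2.31, Chchd6 at 2.30 and the haemoglobin gene Hbb-bs at 2.26. Corrected, Cntd1 (3.94), Hddc2 (1.26) and Chchd6 (1.93) were still called, and Saa1 (2.23, adjusted p = 0.103), Pla2g5 (2.32, 0.0552), Defa-ps1 (0.61, 0.318), Vip (1.32, 0.0803) and Hbb-bs (1.25, 0.0684) were not. Calls also ended without Post 2'-FL 1 for Cntd1 (4.06) and Saa1 (2.08), without Post control 1 or 3 for Saa1 (2.94 and 2.86), and without Post control 1 or 3 or Post 2'-FL 1 or 3 for Pla2g5 (2.20, 2.29, 2.24 and 2.30). The other largest decreases were the transcription regulator Spen at -3.15, the RNA polymerase subunit Polr2a at -3.00, Gltscr1 at -2.83, Ankrd52 at -2.65, the receptor Erbb3 at -2.65, the histone demethylase Kdm6b at -2.64, the histone methyltransferase Setd1b at -2.63, the acetyltransferase Crebbp at -2.62 and Tnrc18 at -2.60. Their transcripts measure 5360 to 12299 nt, and corrected they lay between -1.45 and -2.34, all called. Without Post control 2 Saa1 was at 5.27, Pla2g5 at 3.15 and Hbb-bs at 2.97, and without Post control 3 Cntd1 was at 5.14, Spen at -2.53 and Crebbp at -2.01. Without Post 2'-FL 2 Polr2a was at -4.25, Gltscr1 at -3.80, Erbb3 at -3.60 and Tnrc18 at -3.20. Fut2 (1.27 ± 0.72, adjusted p = 0.177) and Fabp6 (0.89 ± 2.38) were not called, and Fgf15 had 0 counts in both groups.

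Of 34 oxidative phosphorylation genes 28 were higher with the supplement, with a median of 0.94 and Ndufv2, Ndufb8 and Ndufb9 at 1.44, 1.43 and 1.49; corrected, 9 were higher and 1 lower and the median was 0.23. Of 16 Paneth cell genes 12 were higher, 15 when adjusted over the list alone, with Mmp7 at 2.07 (1.12 corrected) and a median of 1.34. Corrected, 1 was higher and the median was -0.02. Of 23 cell cycle genes 11 were higher and 1 lower, with Birc5 at 1.81, Rrm2 at 1.52 and Ccne1 at 1.67, and 8 were higher when corrected. Of 15 brush border hydrolase genes 6 were lower, and 6 when corrected, with Anpep at -1.61 and Ace at -1.81. Lct, the lactase gene, was at -1.41 and corrected at -0.65, not called. Of 12 sugar and amino acid transporters 5 were lower (2 corrected), with Slc7a8 at -1.98, and of 12 immediate early genes 6 (2 corrected), with Jun at -1.58. Hspa1a was called at -2.88, with 6.47, 36.4 and 84.8 CPM in Post control 1 to 3, and was not called when corrected (-2.26) or without Post control 3 (-1.80). Of 12 clock genes 4 were lower (3 corrected), with Per2 at -1.95 and Npas2 at -1.83 (-2.47 without Post 2'-FL 2). Of 4 red blood cell genes 3 were higher (1 corrected), with Hba-a2 at 2.15 (1.32 corrected, not called). These 8 lists passed camera and 0 lists did with an estimated correlation (adjusted p = 0.951 each). Corrected, the Paneth cell (0.827) and clock (0.122) lists no longer passed. Of 104 called list genes examined singly, 42 were not called without at least 1 of the libraries and 52 when corrected. Of 13 smooth muscle genes 5 were higher (4 corrected, median 0.67), of 13 extracellular matrix genes 6 (4 corrected, median 1.07), and of 12 stem cell genes 2 were higher and 2 lower (2 and 0 corrected, median 0.71). These 3 lists passed camera only when corrected (adjusted p = 0.00087, 0.00185 and 0.0392), and not then with an estimated correlation (adjusted p = 0.713 each).

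In all, 5011 genes were called between the Post groups, 2471 higher and 2540 lower with the supplement, and 6667 genes had groups that did not overlap (50.7% where chance gives 10%). The correction left 2853 called, 1334 higher and 1519 lower, and 2220 of them were among the 5011. The number fell to 3279 without Post control 3.

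Pre 2'-FL against Pre control gives the difference between the arms before resection and, by the labels, before the supplement began. Bcmo1, which cleaves beta-carotene (Entrez 63857, chromosome 8, 117095854 to 117133720), averaged 0.664 ± 0.189 CPM in the 2'-FL arm and 7.56 ± 0.51 CPM in the control arm (SD, n = 3), a log2 difference of -3.45 ± 0.38 (SE, adjusted p = 0.00331). The clock gene Per2 (Entrez 18627, chromosome 1, 91415982 to 91459324) averaged 9.88 ± 0.249 and 38.6 ± 14.9 CPM, a difference of -1.97 ± 0.26 (adjusted p = 0.0128). These 2 genes passed, both with 3 lower libraries in the 2'-FL arm and both also when corrected. The 3 next smallest p belong to Hlf (-2.33 ± 0.39), Abcb1b (-1.77 ± 0.32) and Akr1c14 (-2.28 ± 0.42), which did not pass (adjusted p = 0.128 each). Of 12 clock genes 1 was called, and 5 lower and 1 higher when adjusted over the list alone, with Dbp at -2.47 and Per3 at -1.84, which were called over all genes without Pre 2'-FL 1 (-3.24 and -2.42). This list passed camera also with an estimated correlation (adjusted p = 0.00655). The adipose list had a median of 2.76 with 0 genes called over all genes and 6 adjusted over the list alone (adjusted p = 0.298 with an estimated correlation), and its genes were highest in Pre 2'-FL 1, with Cfd at 155 CPM and Car3 at 219 CPM. Reg3b (1.08 ± 0.70), Reg3g (1.14 ± 0.72), Fut2 (2.25 ± 0.68, adjusted p = 0.868), Fabp6 (-3.31 ± 1.34) and Fgf15 (-0.10 ± 0.88) were not called.

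At an unadjusted p under 0.05 there were 445 such genes between the Pre groups, DESeq2 called 24 and limma-voom 3. The number of called genes was 7 without Pre control 3, 17 without Pre 2'-FL 1, 0 without Pre 2'-FL 2 and 1 without Pre 2'-FL 3, and Bcmo1 was not called without Pre 2'-FL 2 (-3.27), nor Per2 without Pre 2'-FL 2 or 3 (adjusted p = 0.107 and 0.15). In both runs the difference of Per2 itself moved by less than its SE. Hlf (-3.02) and Akr1c14 (-3.04) were called without Pre 2'-FL 1, and Abcb1b (-2.05) without Pre control 3. Camera passed 19 of 34 lists with its preset correlation and 1, the clock list, with an estimated one.

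The interaction asks whether the change after resection differed between the arms. As tested it held 2038 genes, 982 with a more positive and 1056 with a more negative change in the 2'-FL arm. With length and GC corrected edgeR called 0, with 2630 genes at an unadjusted p under 0.05 (4273 as tested), and no other program was run with the correction. With the transcript of middle length, the first choice for the correction and replaced after its results were seen, it called 751. The largest positive differences as tested were Akr1c19 (Entrez 432720, chromosome 13, 4228700 to 4252843) at 3.97 ± 0.65 log2 units, Dbp at 3.28 ± 0.98, Ugt2b5, a glucuronosyltransferase, at 2.54 ± 0.79, Akr1c13 at 2.42 ± 0.41 and Ly6d at 2.40 ± 0.67. The largest negative were Irs2 at -4.22 ± 0.71, Cyp2e1, a cytochrome that oxidises ethanol, at -3.69 ± 1.19, Kif13b at -3.23 ± 0.42, Spen at -2.88 ± 0.49 and Erbb3 at -2.81 ± 0.64. Their adjusted p lay between 0.0159 and 0.0488 as tested and between 0.058 and 0.271 corrected. The corrected differences were 2.95, 3.46, 1.68, 1.49 and 1.47, and -3.26, -4.24, -2.45, -1.59 and -2.13, in the same order. Of 34 oxidative phosphorylation genes 24 differed, with a median of 1.13, and of 16 Paneth cell genes 1, with a median of 1.16. Corrected, 0 did in either list and the medians were 0.33 and -0.13. As tested both lists passed camera and neither did with an estimated correlation (adjusted p = 0.942 each). Corrected, 9 lists passed camera, among them oxidative phosphorylation (adjusted p = 0.000545) and not the Paneth cell list (0.929), and 0 with an estimated correlation (adjusted p = 0.976 each). Reg3b (2.33 ± 0.99, adjusted p = 0.118), Reg3g (1.49 ± 1.01, adjusted p = 0.32), Fut2 (-0.98 ± 1.00) and Fabp6 (4.20 ± 2.76) were not called, so a different change of these genes in the arms was not shown.

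The interaction count depended on single libraries: it was 1044 without Pre control 2, 1005 without Pre control 3, 1132, 1245 and 1206 without Pre 2'-FL 1, 2 and 3, 1254 without Post control 1, 424 without Post control 3, 1181 without Post 2'-FL 1 and 1174 without Post 2'-FL 3. Without Post 2'-FL 1 and Pre control 3 together it was 181. Among the named genes, Erbb3 was not called without Post control 3 (-2.64). Ly6d was not called without Pre control 3 (2.23), Pre 2'-FL 2 (2.15), Post control 3 (2.30) or Post 2'-FL 1 (1.83). Dbp was not called without Pre control 3, Pre 2'-FL 3, any 1 of the Post control libraries, or Post 2'-FL 1 or 2 (2.64 to 3.43). Ugt2b5 was not called without Pre control 1 or 2, Pre 2'-FL 2 or 3, Post control 1 or 3, or Post 2'-FL 1 or 3 (1.64 to 2.71). Cyp2e1 was called only without Pre 2'-FL 2 and lay between -2.17 and -4.34 without any 1 of the other libraries, at -2.17 without Pre 2'-FL 1, -2.64 without Post control 3 and -4.34 without Pre control 2. It averaged 40.2 ± 45.0 CPM in Pre 2'-FL and 3.96, 4.12 and 3.39 CPM in Pre control, Post control and Post 2'-FL, so its difference lay between the Pre groups. Dbp also differed mainly there, with 94.4 CPM in Pre control and 16.8 in Pre 2'-FL beside 0.965 and 1.70 after resection. Akr1c19, Akr1c13 and Ugt2b5 averaged lower in Pre 2'-FL than in Pre control and higher in Post 2'-FL than in Post control. Part of their interaction thus lay between the Pre groups. In Pre control and Pre 2'-FL they averaged 49.3 and 8.61, 61.2 and 26.6, and 12.96 and 4.94 CPM in that order. In Post control and Post 2'-FL they averaged 24.9 and 69.8, 72.8 and 169, and 8.56 and 19.5 CPM. Ly6d, Irs2, Kif13b, Spen and Erbb3 differed mainly between the Post groups. Without Pre 2'-FL 1 Dbp was at 4.10 and Ugt2b5 at 3.21, without Post control 3 Spen was at -2.26, and without Post 2'-FL 2 Erbb3 was at -3.76.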

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

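The matched random lists and the tests of the clock genes, of Reg3b and Reg3g and of the length correction were chosen only after the results were seen, and the thinning and the other splits of the libraries before.

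A difference between the arms in the change after resection, tested as an interaction, singled out 2038 genes (982 more positive and 1056 more negative in the 2'-FL arm). Among the named genes these were Akr1c19 (3.97), Dbp (3.28), Ugt2b5 (2.54), Akr1c13 (2.42), Ly6d (2.40), Irs2 (-4.22), Cyp2e1 (-3.69), Kif13b (-3.23), Spen (-2.88) and Erbb3 (-2.81), all in log2 units. The Paneth cell list (median 1.16) and the oxidative phosphorylation list (median 1.13) passed camera with its preset correlation, and neither did with an estimated one (adjusted p = 0.942 each). Corrected, oxidative phosphorylation still passed camera (adjusted p = 0.000545; 0.976 with an estimated correlation). With length and GC corrected edgeR called 0 genes, at 2630 with an unadjusted p under 0.05, and with the transcript of middle length, the first choice and replaced after its results were seen, it called 751. With the longer transcript the 10 genes changed by 2.95, 3.46, 1.68, 1.49, 1.47, -3.26, -4.24, -2.45, -1.59 and -2.13 in the same order. Without Pre 2'-FL 1 Cyp2e1 was at -2.17, Dbp at 4.10 and Ugt2b5 at 3.21, without Post control 3 Cyp2e1 was at -2.64 and Spen at -2.26, and without Pre control 2 Cyp2e1 was at -4.34. Without Post 2'-FL 1, 2 and 3 Dbp was at 2.64, Erbb3 at -3.76 and Ugt2b5 at 1.64. Of 100 splits 5 gave as many genes, the real one included, and the highest other gave 3217, so chance was not excluded. The other 4 splits with as many genes all kept the real Post groups. They retain that difference, so the splits cannot decide on chance. The 7 drawn splits that kept the real Post groups and regrouped only the Pre libraries gave 1575 to 3217 genes. The 8 that kept the real Pre groups gave 0 to 1, and the 84 that kept neither gave 0. The interaction is made of the difference between the Post groups, with 5011 genes called, and that between the Pre groups, with 2. These split counts follow from that and are not separate evidence.

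The first pattern is that lists of short transcripts were higher in Post 2'-FL than in Post control. For oxidative phosphorylation, with every library thinned to the smallest total, the median was 0.95, beside 0.94. Thinning keeps the proportions of genes within a library, so this result cannot decide on library size as a cause. For the Paneth cell list the length and GC trend is a possible explanation, since its median of 1.34 lay at percentile 86.41 of 10000 random lists matched on length, GC and expression (matched median 1.18; percentile 96.11 with the transcript of middle length, which would leave it undecided). The oxidative phosphorylation median lay at percentile 98.91 (matched median 0.57; 99.74 with the transcript of middle length), which left the trend undecided, as the limit set for excluding it was the 99th and the transcript choice was changed after being seen. Whether the trend is from RNA quality, library preparation or the mice cannot be told apart. The labels give no batch, and the trend lies mostly with the groups. An effect of the supplement stays open.

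The second pattern is the clock genes between Pre and Post. In the control arm the length trend is excluded as the whole cause. After correction, the median change of Arntl, Npas2 and Clock there differed by 4.53 log2 units from that of the genes of the opposite phase. This was not tested in the 2'-FL arm, where correction left fewer clock genes called, 3 of 12 lower and 1 higher. The hour of tissue collection, which the labels do not give, is a possible explanation: 6 of 12 clock genes also differed between the Pre groups, adjusted over the list alone, where neither resection nor supplement had been applied by the labels. An effect of resection on the clock stays open and was not tested separately.

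The third pattern is Reg3b and Reg3g, higher in Post 2'-FL than in Post control. The length trend stays undecided: Reg3g was 2.63 ± 0.75 as tested and 1.46 ± 0.64 corrected (adjusted p = 0.116), where its call ended because the fold fell by more than its SE, and Reg3b was 2.20 ± 0.63 corrected (adjusted p = 0.0254); without Post control 2 they were 3.83 and 4.89 as tested. A difference between the arms before resection is also undecided, since the interaction of Reg3b was 2.33 ± 0.99 (adjusted p = 0.118); without Post control 2 it was called (adjusted p = 0.0157), and over the alternatives with all libraries the adjusted p ran from 0.0711 to 0.495. An effect of 2'-FL may underlie the difference and stays open beside both.

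For the comparisons of 3 against 3 libraries 10 splits are too few for a share under 0.05. The control arm gave 1415 genes and the highest other split 4 (1 of 10 splits as many), the 2'-FL arm 7274 and 0 (1 of 10), the Post groups 5011 and 0 (1 of 10), and the Pre groups 2 and 2 (2 of 10). Over both arms 1 of 100 splits, the real one included, gave as many as the real 7416, and the highest other 5675. By the limit of 0.05 set beforehand, chance alone was unlikely for the whole count. The 8 splits that kept the 2'-FL arm's groups gave 971 to 5675, and the 8 that kept the control arm's groups 0 to 1. The 83 that kept neither gave 0 to 3. Splits that keep the 2'-FL groups retain that difference, so this share cannot decide on chance in a single arm.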

How the results depend on the processing

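The length and GC corrections, the removal of Esp38 and Lars2 and the removal of 2 libraries were chosen only after the data were seen, and the transcript of the correction was changed after its first results. Causes were not tested except where fewer samples or another threshold are the cause by construction.

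Counts that moved by more than 1.5 times were these. With length and GC corrected the 2'-FL arm had 4681 genes, the Post groups 2853 and the interaction 0. With the replicate block added they had 4613, 2712 and 0 (2610 at an unadjusted p under 0.05), and with the transcript of middle length the interaction had 751. Removing 2 libraries left 570 in the control arm, 8 between the Pre groups and 181 in the interaction. An adjusted p under 0.1 gave 2562 in the control arm and 3281 in the interaction. A change of at least 2-fold left 928 in the control arm, 2837 over both arms and 2776 between the Post groups. Arm by replicate number as a block gave 901 in the interaction, although correlations between same-numbered libraries of the same arm (-0.12 to 0.22) do not show pairs. Between the Pre groups DESeq2 gave 24, no count filter 12, the stricter filter 1 and a fit of only the groups compared 1. Leaving out each library gave 265 to 1843 in the control arm, 3279 to 5384 between the Post groups, 0 to 17 between the Pre groups and 424 to 3024 in the interaction. The 2'-FL arm (6215 to 7375) and both arms (6653 to 7478) stayed within 1.5 times.

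Of 34 lists, camera with an estimated correlation called 0 in the control arm, 0 in the 2'-FL arm, 0 over both, 0 between the Post groups, 1 between the Pre groups and 0 in the interaction. Fry called 4 in the control arm, 10 in the 2'-FL arm, 3 between the Post groups, 1 between the Pre groups and 1 in the interaction. Corrected, 7 were called in the 2'-FL arm and 9 in the interaction, and 5 in the interaction with arm by number as a block. Leaving out each library gave 2 to 5 in the 2'-FL arm and 2 to 6 in the interaction.

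Directions reversed for few of the values that passed in at least 1 of the 2 settings compared. Between the Pre groups, leaving out each library gave camera adjusted p values of 1.24e-06 to 0.924 for the Paneth cell list and 2.2e-05 to 0.664 for fat absorption, both turned without Pre 2'-FL 2 (0.00811 and 0.664). The range was 0.00217 to 0.374 for T cell, turned without Pre control 2 (0.0286). It was 0.00703 to 0.973 for myeloid and 1.22e-05 to 0.396 for extracellular matrix, both turned without Pre control 1 (0.00703 and 0.205). In the interaction the Paneth cell list turned when corrected (0.929). Corrected, and then also blocked, log2 changes in the 2'-FL arm were -0.0965 and -0.0454 for Igj, 0.00159 and 0.00227 for Itgam, -0.0451 and -0.0359 for Reg3a, -0.66 and -0.62 for Rgs13, and 0.0990 and 0.13 for Synm; with the transcript of middle length Itgam was 0.0772 and Rgs13 -0.20. Between the Post groups they were -0.39 and -0.39 for Agr2, -0.0143 and -0.0382 for Defa5, -0.26 and -0.25 for Gcg, -0.27 and -0.26 for Rgs13, -0.15 and -0.14 for Sar1b and -0.0425 and -0.0517 for Slc51b, with Kitl at -0.0539 for the transcript of middle length. In the interaction Agr2 was at -0.0561 and -0.0532.

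Of 738 values of named and listed genes, 578 kept direction and side of the threshold when corrected, 144 no longer passed, 4 newly passed and 12 reversed; with RLE factors 731 did, and with limma-voom 693. Depth limits genes at a few counts, such as Fgf15 after resection, to bounds.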

Other observations

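These values were noticed in the data, and no test of an explanation was run on them. The nuclear RNA Neat1 stood at 24.3, 38.2 and 37.0 CPM in Pre control and at 219, 26.3 and 32.4 in Pre 2'-FL. In Post control it was at 203, 183 and 165 CPM and in Post 2'-FL at 104, 127 and 79.1. Pre 2'-FL 1, the Pre library at 219 CPM, is also the one in which the fat tissue genes Adipoq (48.5 CPM), Cfd (155 CPM) and Car3 (219 CPM) were highest.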
